A study of Monodelphis domestica with 25 samples.

How the data were processed

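Whole blood of the gray short-tailed opossum (Monodelphis domestica, LSD strain), a marsupial laboratory animal, was cultured outside the body, and its poly(A) RNA was sequenced with a strand-keeping kit. Per the labels, a pilot time course held 15 libraries of untreated blood at 0, 12, 24, 48 and 72 h, with the identifiers A0036, A0039 and A3538 at each time. The design text counts 1 library fewer. The pilot blood was diluted at 2 strengths that the labels do not tie to libraries. The treatment experiment held 10 libraries, 4 controls, 4 with perfluorooctanoic acid (PFOA) and 2 with GenX, at 12 or 24 h. Per the labels' protocols, all treated and control cultures contained 0.1% dimethyl sulfoxide. The controls are nevertheless labelled untreated, so whether they held the solvent is not certain. The words low and high in the PFOA titles were read as 400 and 800 µM, and high in the GenX titles as 1200 µM, because the protocol lists a smaller and a larger concentration of each compound. All titles of the treatment experiment share the identifier A9394 with the numbers R1 to R4, and the labels do not say whether these stand for animals or wells, so p-values there measure the spread between these cultures, which may be technical.

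The authors deposited 1 table of raw read counts per transcript for each experiment. The deposited counts are whole numbers that were not normalized. Per the submitters' processing notes, the tools used were FastQC 11.5, Trimmomatic 0.36, TopHat2 2.1.1, Bowtie2, bedtools 2.30.0, edgeR and R 4.1.2. The genome build, the annotation release and whether strand entered the counting are not given in the sources used here, so transcripts that overlap, lie antisense to each other or share reads with near-identical copies are uncertain. Each table held 22063 features, of which 22049 carried an Ensembl transcript identifier and 14 carried another name. None of the identifiers occurred in the reference gene table used here (assembly mMonDom1.pri, 0 matches), and the files do not pair them with gene names, so no gene name was given to an identifier and at most 2 identifiers that rose and 2 that fell are printed per comparison. Of the 14 other names, 4 were upper-case copies of another name with identical counts and were removed, which left 22059 features. Among values of 1 to 12 counts, 71.0% in the time course and 70.9% in the treatment experiment were even, so single counts were not independent and counting intervals are too narrow.

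Library totals ranged from 51349217 to 336472834 counts in the time course and from 366269 to 11685427 in the treatment experiment. A floor of 3 counts in a library corresponded to 0.0169 to 0.0689 CPM (counts scaled to a common library total, here with TMM factors) in the time course and to 0.239 to 9.52 CPM in the treatment experiment. Shares of a library carry 95% Clopper-Pearson intervals, pooled count ratios carry exact Poisson intervals, and both, like the floors, cover counting error only.

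The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the deposited counts, with TMM normalization, filterByExpr on the groups (minimum count 10) and Benjamini-Hochberg adjustment, and a transcript was called at an adjusted p under 0.05. Time course contrasts came from 1 model of all 15 libraries with time as a factor (15524 transcripts tested). Treatment contrasts came from 1 model of all 10 libraries with treatment and time (12565 tested), the dose contrast added a dose term, and the change of the PFOA effect with time was an interaction term in the 8 control and PFOA libraries (10940 tested). CPM values are TMM-scaled unless given as a share of the total. Composition measures were compared by exact two-sided permutation tests, 35 in all, with Benjamini-Hochberg adjustment.

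On counts simulated from the real means, library sizes and dispersions with 200 changed transcripts, the test recovered 0% of 2-fold and 71.0% of 4-fold changes for 12 against 0 h, 13% and 81.5% for PFOA, 0.5% and 66.0% for GenX, and 0% and 6% for the interaction. The changed transcripts were drawn from those above a minimum expected count, so these shares do not cover lower ones. They hold for 200 changes. In the real 12 against 0 h comparison, 889 of 1191 calls were at least 2-fold, so smaller changes were called there. A list raised 1.5-fold in simulated PFOA libraries had p = 3.6e-43 by camera and 8.29e-06 with an estimated correlation, and the 4 unchanged lists had p from 0.578 to 0.885 by camera. The simulated transcripts varied independently, so this cannot show how camera behaves on lists whose members vary together.

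Choices made before the data were examined included the groups, the tests, most alternatives and the rule for named transcripts. That rule took the largest fold changes among called transcripts with a mean of at least 5 CPM in the higher group and no overlap between the groups, in the 4 main comparisons (12 against 0 h, 24 against 12 h, PFOA and GenX against control). It was to take 8 per direction with a gene symbol, and 2 identifiers per direction were taken because symbols could not be had. All tested features with another name were added after the data were seen, as were the calls of comparisons with 5 or fewer. The planned gene lists, cell type markers, haemoglobin and mitochondrial shares, and removal of haemoglobin could not be run without gene names. Their place was taken, after the data were seen, by lists of transcripts called in the time course (tested with camera, camera with an estimated correlation, and fry) and by removal of transcripts with over 5% of any library.

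Alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a 2-fold threshold, the identifier or number as a replicate block, narrower sets of libraries, no time covariate and leaving out each library. Added later were thinning of every library to the smallest total of its experiment, removal of abundant transcripts, and leaving out the 24 h high-dose PFOA library. The list tests were also run on the thinned libraries. The identifiers of the time course were read as blood donors that recur at each time. Deviations from the time means correlated with a median r of 0.201 in the 30 same-identifier pairs, 22 of them over 0.1, and of -0.0992 in the 60 other pairs. Deviations within a time cancel out, so the value of the other pairs mirrors the first and is no separate reference.

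Some tests were run and left out. An exact permutation test of list means was dropped because libraries had been centred on controls before permuting. A comparison that looked for a near-identical copy of 1 transcript was dropped, with its prediction, after its result was seen, because it compared libraries chosen by their measured level, and a prediction of that transcript's count was recomputed from the time course for the same reason. A correlation between libraries of the same number was dropped, with its prediction, as a test of the source of the PFOA blood, because deviations from group means remove a source shared by a group. A test for treatments swapped between wells was dropped in the same way, because its transcripts had been chosen for no overlap between the treatments. The splits of the treatment libraries by time were redrawn after an error had merged distinct splits.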

Results

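The data were transcript counts from cultured whole blood of the gray short-tailed opossum. An untreated time course (0, 12, 24, 48 and 72 h, 3 libraries per time) asked how the blood transcriptome changes in culture. A second experiment asked how blood responds to 2 per- and polyfluoroalkyl compounds. PFOA is a perfluorinated carboxylic acid, and GenX is the ammonium salt of a perfluorinated ether acid made as its replacement. The treatment experiment held 4 control libraries (12 and 24 h, 2 each), 4 PFOA libraries (400 and 800 µM, each at 12 and 24 h) and 2 GenX libraries (1200 µM, 12 h). Total counts per library were 51349217 to 336472834 in the time course, 4487453 to 11685427 in the controls, 3654215 and 6433771 with GenX, and 366269 to 4027470 with PFOA. The files name almost all transcripts by identifier only, without gene names.

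Fresh blood was dominated by very few transcripts, and this dominance was lost in culture. The most abundant transcript, ENSMODT00000014407, held 27.6% ± 12.9 (SD, n = 3) of the counts at 0 h, 24.6% ± 16.1 at 12 h, 15.3% ± 12.3 at 24 h, 1.52% ± 2.12 at 48 h and 0.780% ± 1.14 at 72 h. The second, ENSMODT00000021124, went from 13.1% ± 7.10 to 0.361% ± 0.558 over the same period. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, ENSMODT00000014407 fell by 5.53 on the log2 scale from 0 to 48 h (adjusted p = 0.0347) and fell by 6.48 from 0 to 72 h (adjusted p = 0.0124). The 48 h call was lost without the 0 h library of A0036 (adjusted p = 0.0747) or A3538 (0.0604) or the 48 h library of A0036 (0.116) or A0039 (0.0916), and without the 48 or the 72 h library of A3538 the log2 fold change was -7.74 or -9.07. The 10 most abundant transcripts together held 48.3% ± 22.3 at 0 h and 16.0% ± 1.36 at 72 h, and detected transcripts numbered 15150 to 16220 at 0 h and 17003 to 17522 at 72 h. The exact permutation test (two-sided, n = 3 per time) did not use the identifiers and gave p = 0.1 for these 0 and 72 h differences, the smallest that 3 against 3 allows, and 0.318 after adjustment over 35 tests. The identifiers differed throughout, and A0039 had the lowest share of ENSMODT00000014407 at every time, from 12.7% (95% Clopper-Pearson interval 12.7 to 12.7) at 0 h to 0.0381% (0.0377 to 0.0384) at 72 h.

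**Figure D1:**
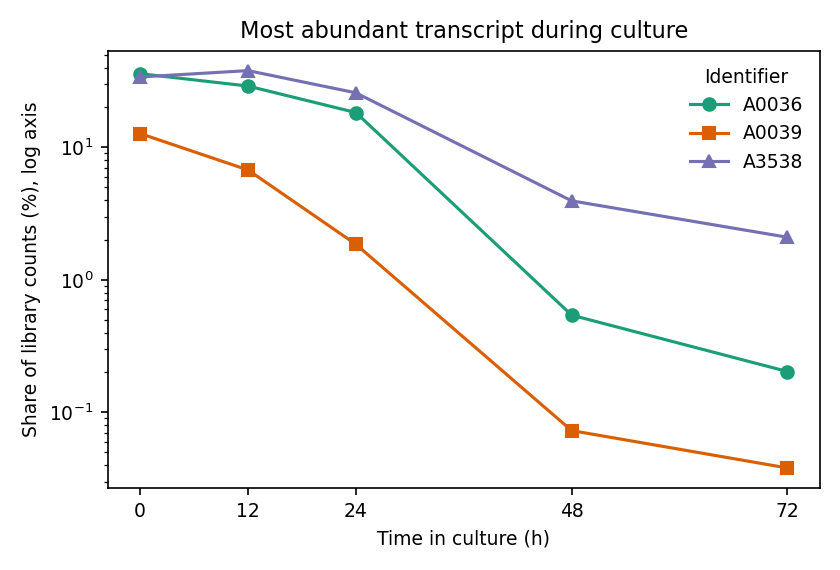
Share of all counts in a library (percent, log axis) held by the most abundant transcript against time in culture (h), 1 line per identifier and 1 point per library. The share went from 12.7 to 35.98% at 0 h down to 0.0381 to 2.097% at 72 h.

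The first 12 h of culture changed the level of 1191 of 15524 transcripts, 631 upward and 560 downward. ENSMODT00000008242 had no count in any 0 h library and reached 184 CPM ± 65.5 (SD, n = 3) at 12 h, at least 3920-fold above the level of 3 counts per library. ENSMODT00000000937 likewise went from 0 to 17.6 CPM ± 15.3, at least 376-fold, and was at 0.0775 to 0.305 CPM at 48 h and at 0, 0.548 and 6.77 CPM at 72 h. In the other direction, ENSMODT00000027399 dropped from 355 CPM ± 250 to 1.00 CPM ± 0.0973 (log2 fold change -8.47, SE 1.15, adjusted p = 0.000731, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and ENSMODT00000015756 dropped from 6.19 CPM ± 5.77 to 0.0397 CPM ± 0.0580 (-7.26, SE 1.99, adjusted p = 0.0472). DESeq2 called 2102, and the count was 450 without the 12 h library of A0036, 600 without that of A3538 and 728 without the 0 h library of A0036. The call of ENSMODT00000015756 ended when either of the 0 h libraries of A0036 and A3538 or any 12 h library was left out, and that of ENSMODT00000000937 ended without the 0 h library of A0036 (adjusted p = 0.0613).

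Differences from fresh blood grew with time in culture. Against 0 h, 2043 transcripts were called at 24 h (1103 higher, 940 lower), 4616 at 48 h (2460 and 2156) and 7658 at 72 h (3871 and 3787), the last being 49.3% of those tested. At 72 h the median called change was 1.65 on the log2 scale, and 5743 calls were at least 2-fold. The 24 h count was 3080 by DESeq2, 977 without the 24 h library of A0036 and 1084 without that of A0039. The 48 h count was 2994 without the 48 h library of A0036, and the 72 h count was 4984 in a model of the 2 times alone.

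Among the comparisons of successive times from 12 h on, that of 72 against 48 h had the most calls. From 12 to 24 h, 32 transcripts were called (25 higher, 7 lower). ENSMODT00000017266 rose from 0.915 CPM ± 0.367 to 15.7 CPM ± 4.91 (log2 fold change 4.097, SE 0.637, adjusted p = 0.0195, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and ENSMODT00000016773 rose from 1.15 CPM ± 0.345 to 18.2 CPM ± 10.8 (3.98, SE 0.695, adjusted p = 0.034). ENSMODT00000014668 fell from 176 CPM ± 82.8 to 29.4 CPM ± 2.74 (-2.58, SE 0.432, adjusted p = 0.0274), and ENSMODT00000026346 fell from 7.001 CPM ± 0.838 to 1.07 CPM ± 0.0947 (-2.70, SE 0.459, adjusted p = 0.0299). From 24 to 48 h, 8 were called (3 higher, 5 lower), and from 48 to 72 h, 1659 (635 higher, 1024 lower).

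With the identifier as a block, 127 transcripts were called from 12 to 24 h and 459 from 24 to 48 h, while DESeq2 called 254, 877 and 2654 for the 3 successive comparisons. The 12 to 24 h count was 2 without either the 12 or the 24 h library of A0036 or the 12 h library of A0039, 11 without the 24 h library of A0039 and 18 without the 12 h library of A3538. All 4 named transcripts of that comparison lost their call without any of the 12 and 24 h libraries of A0036 and A0039 (adjusted p = 0.0713 to 0.217). ENSMODT00000026346 also did so without either library of A3538 (0.0569 and 0.0965), ENSMODT00000016773 without its 12 h library (0.104) and ENSMODT00000014668 without its 24 h library (0.107). The 24 to 48 h count was 316 without the 48 h library of A3538, 2 without that of A0039 and 0 without any of the other 4 libraries, and with abundant transcripts removed it was 13, of which 61.5% were higher in place of 37.5%. The 48 to 72 h count was 721, 890 and 975 without the 48 h libraries of A3538, A0039 and A0036, 962 without the 72 h library of A0039, and 174 in a model of these 2 times alone.

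**Figure D2:**
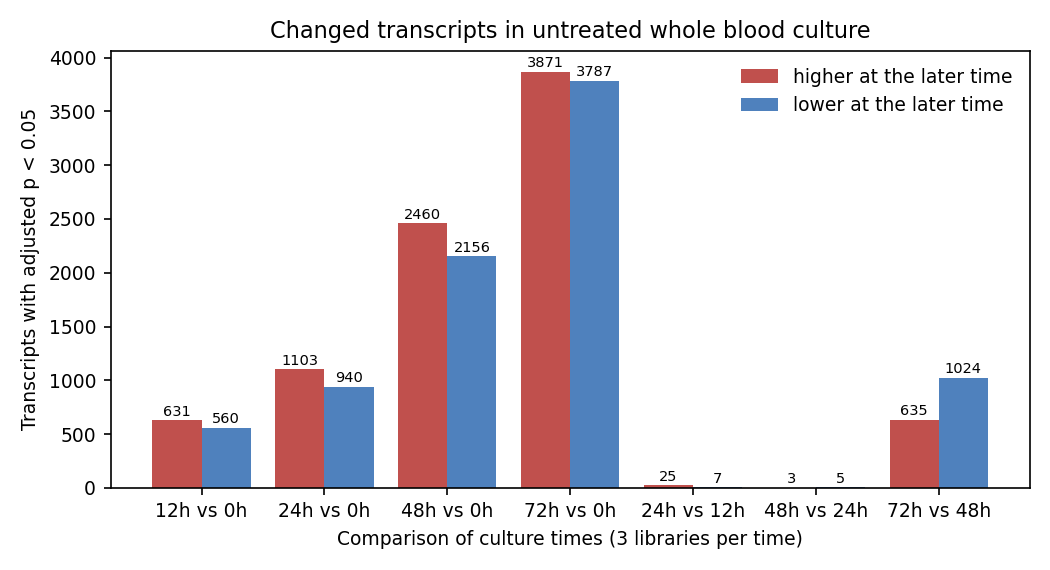
Number of transcripts with adjusted p under 0.05 in each comparison of culture times (3 libraries per time), with bars for transcripts higher and lower at the later time. Counts against 0 h went from 631 and 560 at 12 h to 3871 and 3787 at 72 h, and 25 and 7 transcripts differed between 12 and 24 h.

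A few features carried names in place of identifiers, and 9 of them were tested in the time course. Phlda2_trans, named after an imprinted growth-restraining gene of eutherian mammals, fell from 12.1 CPM ± 2.68 at 0 h to 1.79 CPM ± 1.39 at 48 h (log2 fold change -2.75, SE 0.781, adjusted p = 0.0176, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and was at 13.6 CPM ± 11.2 at 72 h (2.92 against 48 h, SE 0.786, adjusted p = 0.0316). The rise to 72 h lost its call without the 72 h library of A0039 (adjusted p = 0.145) or the 48 h library of A0039 (0.0688) or A3538 (0.0892), and in a model of the 2 times alone (0.136). Tnsf1 fell from 3.63 CPM ± 1.17 at 0 h to 1.06 CPM ± 0.285 at 72 h (-1.78, SE 0.448, adjusted p = 0.00532). Fsnt3 rose from 1.03 CPM ± 0.246 to 2.42 CPM ± 1.07 over the same time (1.23, SE 0.384, adjusted p = 0.0172), a call lost without the 0 or 72 h library of A0039 (0.0576 and 0.0876) and in a model of the 2 times alone (0.0729). Fsnt1 (-1.12, adjusted p = 0.0457) kept its call in only 4 of 14 alternatives. H19_trans, Igf2_trans, Peg10_trans and Cdkn1c_trans, named after other imprinted genes, did not pass the test in any comparison, with adjusted p = 0.062 or more.

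In the treatment experiment, PFOA libraries were smaller and more dominated by abundant transcripts than controls. Their totals were 366269, 754708, 2412085 and 4027470 counts against 4487453 to 11685427, and their 10 most abundant transcripts held 10.4% ± 5.98 (SD, n = 4) against 4.78% ± 0.264 (n = 4). ENSMODT00000014407 held 0.459 to 0.570% of control libraries, 0.849 and 1.29% at 400 µM PFOA, 5.00 and 5.51% at 800 µM PFOA, and 0.561 and 1.39% with GenX. The exact permutation test (two-sided, n = 4 and 4) gave p = 0.0286 for each of these 3 measures between PFOA and control, the smallest that 4 against 4 allows, and 0.25 after adjustment over 35 tests. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change of ENSMODT00000014407 with PFOA was 2.77 with adjusted p = 0.0898 and did not pass. It passed in DESeq2 (adjusted p = 0.0223), with no low-count filter (1.14e-25) and without either library at 400 µM (0.0342 and 0.0383). With every library thinned to 366269 counts, the rank correlation with the controls of the same time was 0.939 between the 12 h controls and 0.914 between the 24 h controls. It was 0.930 and 0.909 for the 12 h PFOA libraries at 400 and 800 µM, 0.855 and 0.687 for those at 24 h, and 0.932 and 0.900 for the GenX libraries.

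**Figure D3:**
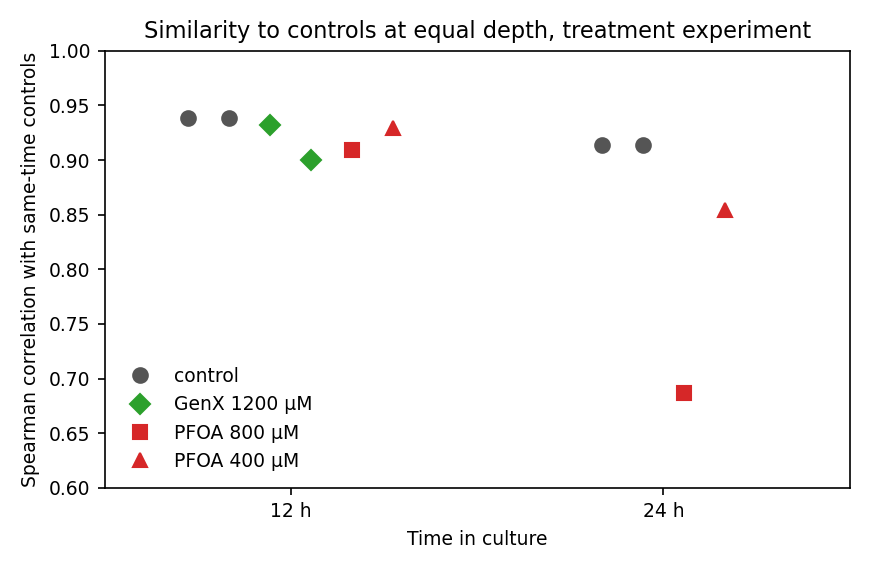
Mean Spearman correlation across transcripts between each library and the control libraries of the same time, after thinning to equal depth, with 1 point per library at 12 and 24 h (the axis starts at 0.6). The 24 h PFOA library at 800 µM was lowest at 0.687.

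A pair of transcripts was far lower in PFOA libraries than in controls. ENSMODT00000001267 was at 63.6 CPM ± 5.16 (SD, n = 4) in controls and at 0.871, 0, 0.964 and 2.50 CPM in the PFOA libraries (log2 fold change -5.84, SE 0.412, adjusted p = 4.84e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The 4 PFOA libraries held 8 counts of it together, 1.66% (exact Poisson interval 0.715 to 3.28) of the control level. ENSMODT00000003531 went from 16.4 CPM ± 1.03 to 1.25 CPM ± 1.35 (-4.09, SE 0.543, adjusted p = 0.0106), with 7 counts in all PFOA libraries together, 5.72% (2.29 to 11.9) of the control level. The 24 h library at 800 µM held 1 count of ENSMODT00000003531 where the mean control level predicts 5.17, too few to show its absence there. In the untreated time course both were also low in fresh blood, at 0.0571 to 0.781 CPM and 0.319 to 1.355 CPM at 0 h, and were at 97.5 to 148.5 CPM and 156 to 254 CPM at 12 h. In all, 10 of 12565 transcripts were called, 7 higher and 3 lower. DESeq2 called 734 (549 higher), the split was 2 higher and 2 lower with RLE size factors, 2 and 3 with abundant transcripts removed, and 1 higher and 9 lower in the 12 h libraries alone. The count was 92 without the 24 h library at 800 µM, 32 without the 12 h library at 400 µM, 3 without either 24 h control, and 1 without the 12 h library at 800 µM or the 12 h control R2. ENSMODT00000003531 lost its call without either of these last (adjusted p = 0.169 and 0.0958), and in the 24 h libraries alone neither of the pair passed (adjusted p = 0.332 for both).

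With GenX, 1 transcript was higher than in controls. ENSMODT00000008287 was at 33.7 CPM ± 2.72 (SD, n = 4) in controls and at 146 and 215 CPM in the GenX libraries (log2 fold change 2.60, SE 0.289, adjusted p = 0.00234, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). No other transcript was called of 12565, while 857 had an unadjusted p under 0.05 and DESeq2 called 63, 61 of them higher. The GenX libraries were numbered R3 and R4 and the 12 h controls R1 and R2, and only a 24 h control shared R3. At 12 h GenX therefore cannot be told apart from the number, and with the number as a replicate block no transcript was called. Without GenX library R4 there were 0 calls (ENSMODT00000008287 then had adjusted p = 0.106), and without R3 there were 69, all higher.

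PFOA and GenX libraries differed in both transcripts that were far lower with PFOA. ENSMODT00000001267 was at 41.8 and 63.5 CPM with GenX, and its PFOA minus GenX difference was -5.59 on the log2 scale (95% interval -6.56 to -4.61, adjusted p = 3.7e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ENSMODT00000003531 was at 15.7 and 20.04 CPM with GenX (difference -4.23, interval -5.5 to -2.96, adjusted p = 0.0149). The third called difference, chosen after its values were seen because only 3 passed, lay between 15.6 and 16.7 CPM in controls, was at 62.6 and 80.2 CPM with GenX, and was at 1.74, 1.93, 6.25 and 12.7 CPM with PFOA. It differed by -4.62 (interval -5.68 to -3.56, adjusted p = 0.000752), although neither compound passed against control (adjusted p = 0.0759 and 0.204), and the call was lost with every library thinned to equal depth (log2 difference -4.55, adjusted p = 0.641). ENSMODT00000008287 had a log2 fold change of 0.82 with PFOA and 2.60 with GenX, and the difference did not pass (-1.78, interval -2.42 to -1.15, adjusted p = 0.0746). Concentrations differed (400 and 800 against 1200 µM), and GenX was measured at 12 h only, where the 12 h libraries alone gave 6 calls, all lower with PFOA. PFOA libraries were numbered R1 or R2 and GenX libraries R3 or R4, so this direct comparison cannot part the compound from the number. With the number as a replicate block there were 0 calls. For most transcripts the data do not show that the compounds acted alike. The 95% interval of the difference had a median width of 1.02 log2 units to either side, and it lay within 2-fold for 27.1% and within 4-fold for 68.7% of transcripts. The count was 7 without the 24 h PFOA library at 800 µM, and ENSMODT00000003531 lost its call without either GenX library (adjusted p = 0.0671 and 0.0848) or either 12 h PFOA library (0.232 and 0.301).

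**Figure D4:**
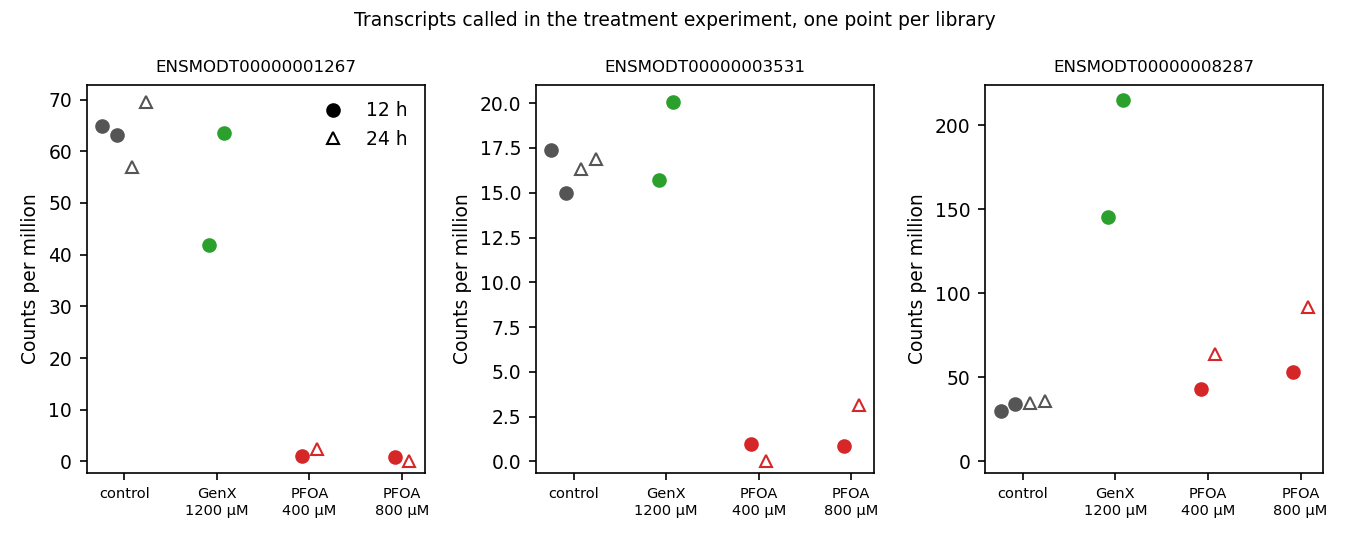
Level (CPM) of 3 transcripts in every library of the treatment experiment, by treatment (filled circles 12 h, open triangles 24 h). ENSMODT00000001267 and ENSMODT00000003531 were at or below 3.17 CPM in all PFOA libraries, and ENSMODT00000008287 was at 146 and 215 CPM with GenX.

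Across transcripts, the fold changes of both compounds against the same 4 controls correlated with Pearson's r of 0.655 and Spearman's rho of 0.599, with the same sign for 72.7%. Transcripts are not independent replicates, and the controls are shared. Libraries simulated with no effect gave r of 0.332 (0.295 to 0.369 in 20 simulations), rho of 0.342 and the same sign for 62.6%. The simulated transcripts varied independently of each other. The range over the simulations therefore leaves out variation that transcripts share and is too narrow as a reference for chance. Splitting the controls between the compounds gave a mean r of 0.483 over 4 ways, with rho of 0.348 and the same sign for 60.9%. The simulations shared all controls, so they give no reference for the split. The covariance was 0.668, against 0.133 simulated and 0.661 with split controls.

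Within PFOA, 2 transcripts differed by dose, both higher at 800 than at 400 µM. ENSMODT00000014426 was at 1347 and 1865 CPM at 800 µM, at 287 and 214 CPM at 400 µM and at 124 to 171 CPM in controls (log2 fold change high against low 2.67, SE 0.355, adjusted p = 0.0144, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ENSMODT00000038822 was at 209.9 and 609 CPM at 800 µM and at 50.1 and 63.7 CPM at 400 µM (2.68, SE 0.382, adjusted p = 0.0165). In the time course, ENSMODT00000014426 was at 5575 to 53640 CPM at 0 h and at 12.1 to 371 CPM at 72 h, and ENSMODT00000038822 at 1312 to 19370 CPM and 2.05 to 53.6 CPM. Both were chosen after their values were seen, because only 2 passed. DESeq2 called 92. The count was 1707 (599 higher) without the 12 h library at 800 µM, 1 without the 24 h library at 800 µM, and 0 without either library at 400 µM. ENSMODT00000038822 was the transcript that lost its call without the 24 h library at 800 µM (adjusted p = 0.165).

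Far more transcripts differed between 12 and 24 h in the treatment experiment than between either compound and control. Both 12 h PFOA libraries were numbered R2 and both 24 h ones R1, so time within PFOA cannot be told apart from the number. The 24 h control and PFOA libraries also had smaller totals than the 12 h ones of the same group. From 12 to 24 h, 1257 of 12565 were called in the treatment model (616 higher, 641 lower). Rsx, the long noncoding RNA of marsupial X inactivation, was at 3.48 CPM ± 4.74 (n = 6) at 12 h and 17.4 CPM ± 20.4 (n = 4) at 24 h (log2 fold change 3.12, SE 0.731, adjusted p = 0.0177, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), a call lost without the 12 h control R1, the 24 h control R3 or either 12 h PFOA library (adjusted p = 0.0538 to 0.0684). The 24 h PFOA library at 800 µM held 47.6 CPM of it on 15 counts, and without that library the 24 h level was 7.29 CPM ± 3.64 (n = 3) and the log2 fold change 2.54 (adjusted p = 0.0212). The 12 h GenX library R4 held 13.1 CPM of Rsx, above every 24 h library except the PFOA library at 800 µM. In the untreated time course Rsx was at 0.0486 CPM ± 0.0439 (n = 3) at 12 h and 0.0324 CPM ± 0.0352 at 24 h (log2 fold change -0.58, adjusted p = 1). These levels rest on 2 to 15 counts per library at 12 h and 0 to 10 at 24 h. Rsx was thus nearly absent from these libraries, although their totals exceeded those of the treatment experiment. Its change there was poorly determined (SE 1.38) and does not settle the treatment result. Of the transcripts called here and tested in the time course, 743 of 1218 (61.0%) had the same direction there from 12 to 24 h and 941 (77.3%) from 48 to 72 h. Conversely, of 26 transcripts called from 12 to 24 h in the time course and tested here, 14 (53.8%) had the same direction here. Of these 26, 3 were called here in the same direction and 2 in the opposite one. Calls shared with the 48 to 72 h comparison were 44 higher in both and 151 lower in both, where independent lists of these sizes would share 25.2 and 47.9, and those in opposite directions were 8 and 11 (28.0 and 43.1). The count was 2647 by DESeq2 and 2430 without the 24 h PFOA library at 800 µM. It was 584, 374, 803 and 344 without the controls 12 h R1, 12 h R2, 24 h R2 and 24 h R3. Without the PFOA libraries at 12 h 400 µM, 12 h 800 µM and 24 h 400 µM it was 465, 537 and 769. With every library thinned to equal depth, 330 were called. With the number as a replicate block, 42 were called, and Rsx lost its call (adjusted p = 0.139).

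Whether the PFOA effect differed between 24 and 12 h was tested by the interaction term. No transcript of 10940 passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (smallest adjusted p = 0.529), 984 had an unadjusted p under 0.05, DESeq2 called 6, and the fit with no low-count filter called 68. The count was 2174 without the 24 h PFOA library at 400 µM and 2 without that at 800 µM. Of 200 simulated 4-fold changes, 12 (6%) were recovered with 0 false calls, so such simulated changes were rarely called with these libraries.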

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

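All explanations of the 24 h high-dose PFOA library, of the second most abundant transcript and of the transcripts lower with PFOA were tested only after the result was seen, and the splits of libraries were planned, except those balanced over the other factor. Among 36 groups of 4 libraries tested for a value far from the others, 3 were found, where chance gives 1.8. The 12 h control R1 had the highest share of counts in its 10 most abundant transcripts, 5.169% against 4.684% in the next control. Cdkn1c_trans was at 7.498 CPM in the 24 h PFOA library at 400 µM, on 6 counts, against 0.9642 CPM in the next PFOA library. Fsnt1 was at 120.5 CPM in the 24 h PFOA library at 800 µM, on 38 counts, against 7.404 CPM in the next.

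The 24 h PFOA library at 800 µM stood apart from the other libraries. Low depth alone is argued against, since with every library thinned to its total its rank correlation with the 24 h controls was 0.6871, against 0.914 between those controls. Its dose and time of exposure may be the cause, and the 24 h library at 400 µM was intermediate at 0.8545. With 1 library at this dose and time, this cannot be told apart from a fault of that culture.

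ENSMODT00000001267 and ENSMODT00000003531 were far lower in the PFOA libraries than in controls. Lower depth is argued against, because the control level predicted at least 17.4 times the pooled counts seen. A variant carried by an individual that the number names is also argued against, since controls with the numbers R1, R2 and R3 lay within 1.22-fold of each other. No label names a batch or another source of blood that goes with PFOA. An effect of PFOA, the difference that the design names, is a hypothesis, since it was found and tested on the same data.

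The second most abundant transcript, ENSMODT00000021124, was nearly missing from 3 libraries of different treatments (15, 48 and 64 counts), although it held 0.151 to 0.592 of the count of ENSMODT00000014407 in the time course. Sampling of few reads is argued against, because the lowest of those ratios predicted 3110 to 18200 counts, at least 113 times the counts seen. A variant of the individual that the number names is argued against too, since the 4 libraries numbered R2 ranged from 3.34 to 1930 CPM of the total, 576-fold. Reads given to a near-identical copy and mixed-up wells stay open, and no other biological explanation was tested.

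Other splits of the same libraries bear on whether the counts could come from chance. In the time course, 10 splits per comparison are too few for a share under 0.05. The real split was 1 of 10 with as many calls in each, with 1191, 2043, 4616, 7658 and 8 calls for 12, 24, 48 and 72 against 0 h and 48 against 24 h, where the highest other split gave 0. For 24 against 12 h it gave 32 against 1, and for 72 against 48 h 1659 against 5. Of the 10 splits, 4 part every pair of libraries with the same identifier, the real one among them. The highest other of these gave 0 in all 7 comparisons, so the 1 and the 5 came from splits that leave some pairs together, and 4 are again too few for a share under 0.05. For PFOA, 1 of 34 splits, the real one, gave 10 calls and the highest other gave 0, with 1 further split that could not be fitted. For 24 against 12 h in the treatment experiment, 1 of 100 drawn splits, the real one, gave 1257 calls and the highest other 11. These shares are under 0.05, but the splits include some that mix times or treatments unevenly. In each comparison 18 splits balance the other factor as the real one does, with 0 calls in the highest other, and 18 are too few for a share under 0.05.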

How the results depend on the processing

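Thinning, removal of abundant transcripts and leaving out the 24 h high-dose PFOA library from the GenX comparison were chosen after the data were seen. No sign changed in 376 alternative values of 26 results of single transcripts (those chosen by the rule, other calls named and ENSMODT00000014407), of which 290 stayed on the same side of the threshold, 82 lost their call and 4 gained one. Nearly all of these results were calls in these same data, and the rule asked for no overlap between the groups. A change of sign was therefore unlikely from the start, and its absence is no evidence of stability. DESeq2 gave 2102, 3080, 254, 877 and 2654 calls for 12 and 24 against 0 h and 24 against 12, 48 against 24 and 72 against 48 h, and 734 for PFOA, 63 for GenX, 10 for PFOA against GenX, 92 for dose, 2647 for 24 against 12 h in the treatment experiment and 6 for the interaction. With no low-count filter, calls were 54 for 24 against 12 h, 40 for 48 against 24 h, and in the treatment experiment 640, 196, 15, 159, 2035 and 68 in the same order. RLE size factors gave 4 for PFOA. With the identifier as a replicate block, calls were 127 for 24 against 12 h and 459 for 48 against 24 h, and in the other time course comparisons the block moved no count by over 1.5 times, and of the named transcripts Fsnt1 alone lost its call (72 against 0 h, adjusted p = 0.0508). With the number as a replicate block in the treatment experiment, where the libraries share only a number (median correlation 0.0318 in 8 pairs, none over 0.1, with signs that groups of 2 libraries mirror), calls were 1 for PFOA, 0 for GenX, 0 for PFOA against GenX, 0 for dose and 42 for 24 against 12 h, where of the named calls ENSMODT00000001267 with PFOA against control alone was kept and the others had adjusted p = 0.0647 to 1 (Rsx 0.139). Models of only the times compared gave 4984 for 72 against 0 h, 67 for 24 against 12 h, 0 for 48 against 24 h and 174 for 72 against 48 h. PFOA had 2 calls with no time covariate and 0 in the 24 h libraries alone, GenX had 2 in the 12 h libraries alone and 3 with controls alone, and PFOA against GenX had 6 in the 12 h libraries alone. With abundant transcripts removed, calls were 13 for 48 against 24 h and 5 for PFOA. Thinned, they were 1 for PFOA, 1 for PFOA against GenX and 330 for 24 against 12 h in the treatment experiment. GenX had 2 calls without the 24 h high-dose PFOA library. Leaving out 1 library at a time gave 450 to 976 calls for 12, 977 to 1802 for 24, 2994 to 4277 for 48 and 6421 to 7433 for 72 against 0 h, 2 to 26 for 24 against 12 h, 0 to 316 for 48 against 24 h and 721 to 2044 for 72 against 48 h. In the treatment experiment it gave 1 to 92 for PFOA, 0 to 69 for GenX, 2 to 7 for PFOA against GenX, 0 to 1707 for dose, 344 to 2430 for 24 against 12 h and 0 to 2174 for the interaction. Where this left a group with 1 library, that library was assumed to vary like the others. Fewer libraries or transcripts entered some of these fits, and otherwise the cause was not tested. Without gene names, removal of haemoglobin and the planned gene list tests were not run. Totals of 366269 to 4027470 counts in the PFOA libraries limit what low transcripts can show.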

Other observations

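The lists of transcripts called in the time course, and the tests of them here, were chosen after the data were seen, with predictions written before their results except for the tests at equal depth, which were added last. Transcripts that fell from 48 to 72 h in the time course had a median log2 fold change of -0.34 with PFOA (923 tested, 24.1% positive, adjusted p = 1.42e-07 by limma's camera, 0.0474 by fry), and those that fell in the first 12 h had 0.33 (473 tested, adjusted p = 7.87e-06 and 0.213). Those that rose in the first 12 h had -0.24 (516 tested, adjusted p = 0.00256 and 0.0092). With an estimated correlation, camera gave these 3 lists adjusted p = 0.248, adjusted p = 0.264 and adjusted p = 0.18, so none of the camera calls held. By fry, the list that fell from 48 to 72 h and the list that rose in the first 12 h passed, but at equal depth fry gave each adjusted p = 0.0636. Without the 24 h library at 800 µM the medians were -0.26, 0.19 and -0.20. With every library thinned to equal depth they were -0.26, 0.52 and -0.18 (563, 248 and 280 tested), with adjusted p = 0.169, adjusted p = 0.18 and adjusted p = 0.169 with an estimated correlation. With GenX they were -0.23, 0.31 and -0.12 (camera adjusted p = 2.89e-06, adjusted p = 1.38e-06 and adjusted p = 0.291), and with an estimated correlation adjusted p = 0.278, adjusted p = 0.278 and adjusted p = 0.531. From 12 to 24 h in the treatment experiment, the list that fell from 48 to 72 h had a median of -0.53 and the list that rose then 0.22 (camera adjusted p = 9.87e-12 and adjusted p = 0.00191), with adjusted p = 0.0997 for both with an estimated correlation. In single PFOA libraries at equal depth, the list that fell from 48 to 72 h lay at mean log2 levels of -0.0275 and -0.18 at 12 h (400 and 800 µM) and -0.31 and -0.61 at 24 h relative to controls of the same time, an order that the totals before thinning also had (4027470, 2412085, 754708 and 366269).

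A hypothesis was that PFOA moves expression the way longer culture does. The list that fell late had the predicted direction with a median of -0.336, but the list that rose late had a median of 0.0317 (camera adjusted p = 0.178). At equal depth the latter was 0.168 (camera adjusted p = 0.00672, adjusted p = 0.18 with an estimated correlation), so this stays open. The hypothesis that PFOA reverses the first 12 h of culture met both predicted directions, with medians of -0.239 and 0.333. The prediction also asked for an unadjusted p under 0.05 in both lists by camera with an estimated correlation. This p was 0.0359 for the list that rose and 0.158 for the list that fell (adjusted p = 0.18 and 0.264), so this too stays open. A candidate explanation for the higher share of ENSMODT00000014407 with PFOA was that all transcripts abundant in fresh blood rose together. With the counts as deposited, a rise of all of them is argued against. The 50 others tested were the most abundant at 0 h among the transcripts called lower at 72 h than at 0 h, so they do not cover abundant transcripts that held their level. They had a median log2 fold change of 0.0949 (SD of members 0.748, camera adjusted p = 0.017, adjusted p = 0.279 with an estimated correlation) against 2.77 for ENSMODT00000014407. Their median at equal depth was 0.268 with 62% positive (adjusted p = 0.18 by camera with an estimated correlation). This was above the limit set for that argument, so a smaller common rise is not excluded. At equal depth their mean log2 level relative to controls of the same time was 0.427 and 0.885 at 800 µM (12 and 24 h). At 400 µM it was 0.102 and 0.168. A rise of some of them with ENSMODT00000014407 stays open too, since ENSMODT00000038822, one of the 50, and ENSMODT00000014426 were higher at 800 than at 400 µM PFOA. ENSMODT00000014426 and ENSMODT00000021124 had been left out of the 50 because they had been noticed before.

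The experiments differed at 12 h without any compound. ENSMODT00000014407 held 6.75 to 38.0% of the counts in the time course at 12 h and 0.544 and 0.570% in the 12 h controls. ENSMODT00000008242 was at 111 to 238 CPM in the time course at 12 h and at 0.564 and 0.956 CPM in those controls.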
